A study of Mus musculus with 10 samples.

How the data were processed

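The study measured gene expression in lung RNA of male C57BL/6J mice on Affymetrix arrays. Per the labels' protocols, 40 mice aged 6 weeks were divided into 5 groups of 8 and treated for 20 days. The treatment text calls the same mice years old, which was read as a slip for weeks. One group received no tumour cells and was given water. The other groups were injected with B16F10, a melanoma line of C57BL/6 origin, and then treated with water, with dacarbazine (DTIC, an alkylating drug used against melanoma) at 70 mg/kg per day, or with the compound SQ-diEG at 5 or 25 mg/kg per day. SQ-diEG is known here only by that name. Each group is represented by 2 arrays, 10 in all, and the group and replicate number of every array came from its title. The labels do not say whether an array holds RNA of 1 mouse or of several, so p-values measure only the spread between these samples, which may be technical.

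Per the labels' protocols, biotin-labelled antisense RNA was made from poly(A) RNA with a 3' in vitro transcription kit, hybridized for 16 hours and scanned on a GeneAtlas station. The sources disagree on the RNA input, with 250 ng in the series text and 9.4 µg in the labelling protocol. The probe set and control identifiers have the form used for whole-transcript arrays, whereas the sources describe a 3' kit and 3' arrays. This reading rests on the identifiers alone. Whether the labelled target was the one that the probes were made for stays unknown, and the meaning of every level depends on it. The deposited values are on the log2 scale, 1 value per probe set and array. Per the submitters' processing notes, RMA, Affymetrix Expression Console and Transcriptome Analysis Console were used. Versions, the exact form of RMA and any background step are not given in the sources used here. The medians of the columns lay between 7.39 and 7.48 and genes were not centred. The lowest value of an array lay between 4.32 and 4.45 and the highest between 19.84 and 19.93, and 42 to 73 probe sets per array exceeded 16, above what a linear 16 bit scan stores, so how the upper end of the scale was made stays unknown.

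The table held 28846 probe sets. Of these, 6640 were control probe sets by their names, 19572 had 1 gene symbol in the platform annotation, none had several, and 2634 carried no gene in that annotation and stayed unnamed. All 19572 gene identifiers were found in the NCBI gene table of assembly GRCm38.p6, used only for names, and no symbol needed an update. A gene was represented by its probe set with the highest mean over the 10 arrays, which gave 19505 genes. Genes were tested if that probe set reached its array's 40th percentile of non-control probe sets on at least 2 arrays. That left 19011 genes and removed 494. No coordinates are given because the build behind the array was not named.

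The values were fitted in R 4.3.3 with limma 3.58.1. One group-means model over all 10 arrays (lmFit, then eBayes with its default prior) gave 6 contrasts, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that contrast. The shared estimate of the spread had 5 residual and 51 prior degrees of freedom. Fixed lists of genes, 38 in all, covered processes and cell types of lung and tumour. They held 1083 genes, of which 966 were on the array, and were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists. With an estimated correlation no list passed in any of the 6 comparisons, as with the preset one. The tests, lists, alternatives and rule for naming genes were set before the data were examined. The rule named the 10 genes with the largest change in each direction among those that passed, or, with fewer than 5, the 5 with the smallest unadjusted p, leaving out clone-type names. It also named up to 4 members of each list described, by smallest p, and Pmel, Tyr, Tyrp1, Dct, Mlana, Mki67, Cdkn1a, Sqle and Sftpc in every comparison. A further gene set by the rule is not reported here.

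The code was tested on simulated data with the real genes' means and the spreads from limma's eBayes step. That step, with 51 prior against 5 residual degrees of freedom, draws the genes' spreads close to a common value. Genes were drawn independently, so any correlation between genes is left out. For injected against uninjected water over 19011 genes, log2 changes of 1, 2, 4 and 6 were called for 0%, 5%, 82.5% and 100% of 40 planted genes each, with 4 false calls. A list of 25 genes shifted by 0.25, 0.5 or 1 on the log2 scale reached an unadjusted p under 0.05 in 5, 15 and 20 of 20 simulations. With 2 arrays per group, a log2 change of 2 or less in a single gene was thus seldom called. The typical standard deviation of a gene between arrays of a group was 0.97 on the log2 scale.

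The alternatives were quantile normalization, median centring, no filter or a 60th percentile filter, the mean of a gene's probe sets or each probe set alone, eBayes with trend and robust settings, a fit of only the arrays compared, array weights, the replicate number as a block, other thresholds, and each array left out in turn. Lists were also tested with fry. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.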

Results

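Lung RNA was profiled on 10 arrays, 2 from each of 5 groups of mice. One group carried no tumour cells and received water. The other groups were injected with B16F10 melanoma cells and received water, DTIC, or SQ-diEG at 1 of 2 doses. The levels below are deposited log2 values, given as mean ± SD of 2 arrays. Across genes, which are not independent replicates, the Pearson correlation between any pair of arrays was 0.129 to 0.253. It averaged 0.211 within groups and 0.202 between groups. Lung and melanoma markers lay in the range of the background on these arrays. None of the 26 genes of type II alveolar cells and surfactant exceeded the 95th percentile of the negative-control probe sets on any array, and 24 of 25 melanocyte genes exceeded it on none. Over all genes, 0.3% to 0.4% per array exceeded it. On all 10 arrays the median of the gene probe sets, 7.33 at the lowest, lay below that of the negative-control probe sets, 7.56 at the lowest, and the background probe sets averaged 7.17 to 7.29. As a set the genes are thus not separated from background, and some levels below lie under it. A difference from such a level is not measured from a detected one, also where this is not repeated.

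The first comparison set B16F10-injected against uninjected mice, both given water, and asks what the injected cells changed in the lung. The melanosome protein Pmel averaged 9.44 ± 0.35 (SD, n = 2) in injected lungs and 6.51 ± 0.86 (SD, n = 2) in uninjected lungs, a log2 difference of 2.93 (SE 0.97). Both injected arrays lay above both uninjected arrays for this gene, but it did not pass limma's test over all genes (Benjamini-Hochberg adjusted p = 0.722). Other products of pigment cells differed less. The log2 difference was 1.16 (SE 0.95) for the melanosome protein Mlana, 0.90 (SE 0.97) for Tyrp1 and 0.83 (SE 0.94) for Dct, both enzymes of melanin synthesis, and -0.55 (SE 1.02) for tyrosinase, Tyr. Of the 24 melanocyte and melanoma genes tested, 12 were higher and 12 lower in injected lungs, and none passed, either over all genes or adjusted over the list alone. As a list they gave a mean log2 difference of 0.11 and an adjusted p = 0.992 from limma's camera. Oca2, Gpr143 and Sox10, the next members by p, differed by -1.59, -1.41 and 1.37.

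**Figure D1:**
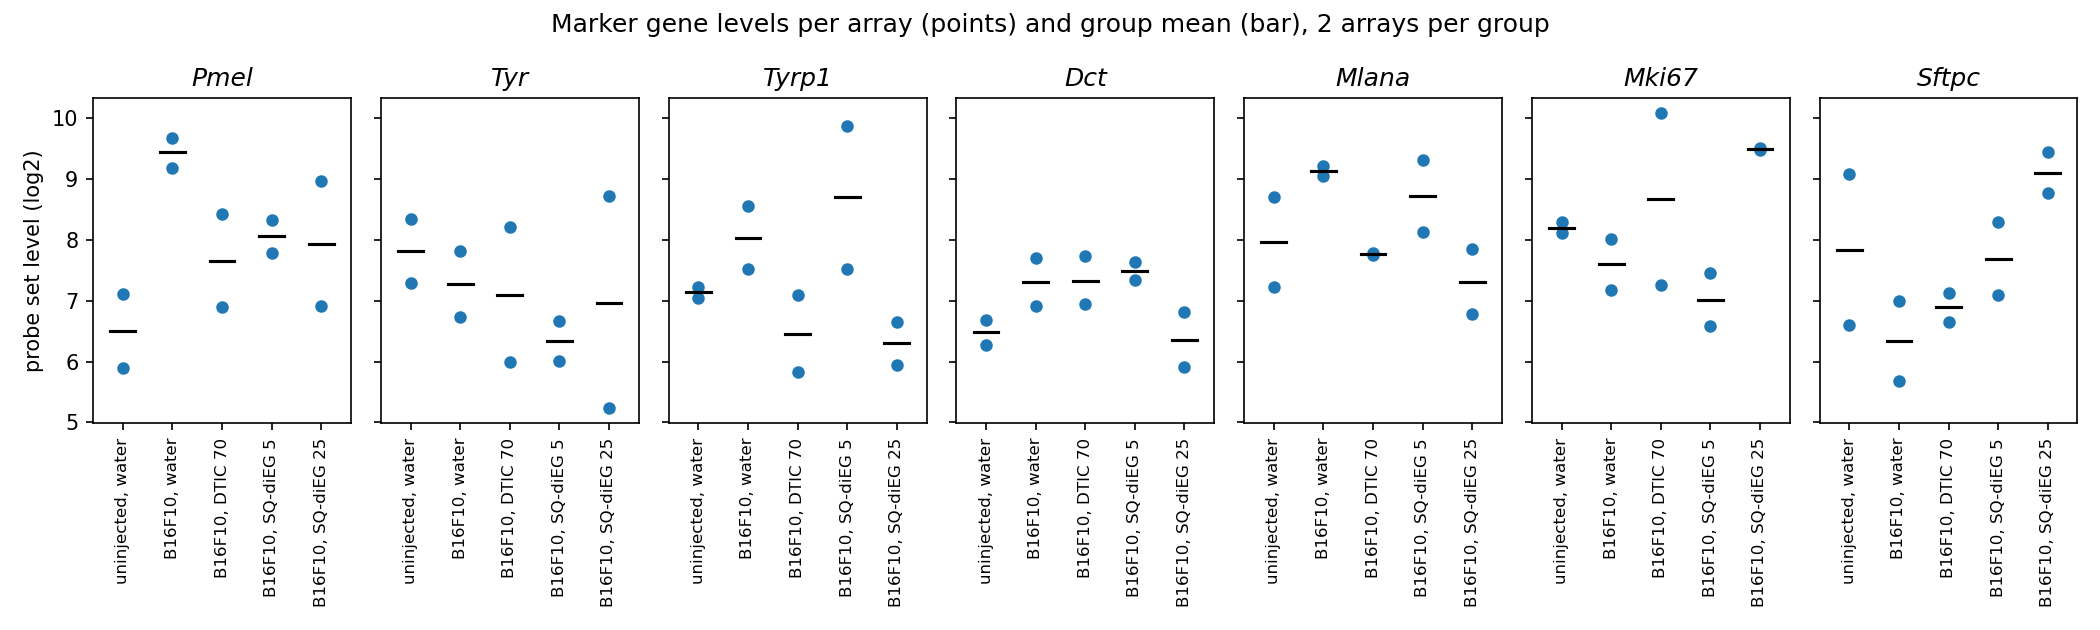
Log2 levels (y axis) of 7 marker genes on each array (points) with the mean of each group (bars), 2 arrays per group. Pmel averaged 9.44 in B16F10-injected mice given water and 6.51 in uninjected mice, and no gene shown passed limma's test in any comparison.

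In the list of antigen presentation by MHC class I, 14 of 22 genes were lower and 8 higher in injected lungs. The mean log2 difference was -0.57. The list was under a p of 0.05 before adjustment and did not pass after it (limma's camera, Benjamini-Hochberg adjusted p = 0.351), and the adjusted p = 0.992 with an estimated correlation. Its members with the smallest p were the chaperone Calr at -2.05 (SE 0.96), the proteasome subunit Psmb9 at -1.90 (SE 0.97), H2-T23 at -1.86 (SE 0.97) and H2-T24 at -1.70 (SE 0.98). Fry, which asks whether the genes of a list move one way without setting them against other genes, gave an adjusted p = 0.00104 for this list. The list's mean hardly varied between the arrays of a group (SD 0.02 in uninjected and 0.04 in injected mice given water). Fry sets the shift against that spread, so its small p rests partly on it. With 2 arrays per group, so small a spread may itself be chance. The hypoxia and glycolysis list had 19 genes higher and 11 lower, with adjusted p = 0.992 from limma's camera. Lactate dehydrogenase A, Ldha, averaged 10.20 ± 0.67 (SD, n = 2) in injected and 7.16 ± 0.10 (SD, n = 2) in uninjected lungs, a log2 difference of 3.04 (SE 0.96). Ankrd37 differed by 2.34 (SE 0.95), Ero1a by 1.72 (SE 0.96) and the vasodilator peptide gene Adm by -2.11 (SE 0.98). None of the 30 genes passed over all genes or adjusted over the list alone, where the smallest adjusted p from limma was 0.0778.

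Proliferation genes were mixed, with 23 of 37 higher. Ube2c differed by -2.55 (SE 0.96), Mcm6 by 2.07 (SE 0.97), Cenpe by 1.88 (SE 0.94) and Prc1 by -1.44 (SE 0.98), while Mki67 differed by -0.60 (SE 0.97). Among immune cell lists, 20 of 29 neutrophil genes were higher, with Stfa1 at 2.23 (SE 1.00), Acod1 at -1.96 (SE 0.97), Stfa2l1 at 1.89 (SE 0.97) and Retnlg at 1.52 (SE 0.98). Of 24 T cell genes 13 were higher, led by Cd4 at 2.23 (SE 1.00), and of 25 NK and cytotoxic cell genes 15 were higher, with Cma1, better known as a mast cell protease, at -2.69 (SE 1.02). The interferon response list had 25 genes higher and 16 lower, with Oas2 at -1.85 (SE 0.94). In the list of type II alveolar cells, whose product surfactant lines the air spaces, 12 genes were higher and 14 lower. Rab27a differed by 2.20 (SE 0.94), Etv5 by -2.29 (SE 1.01), Muc1 by 1.86 (SE 0.98) and the surfactant protein gene Sftpc by -1.50 (SE 0.97). Camera's adjusted p was 0.992 for each of these lists, no member passed over all genes or adjusted over the list alone, and the T cell list's mean and median were above 0 where its camera direction was down. The type II cell list had a median of -0.06 and a mean of 0.01. Cdkn1a differed by 0.66 (SE 1.01) and the squalene epoxidase gene Sqle by -1.40 (SE 0.95). With the hybridization controls as a covariate, a model chosen after the data were seen, the differences of Ipw, Oca2, Sox10, Prc1, Cd4, H2-T23, Mki67, Cdkn1a and Sqle changed sign. The mean of these controls was 8.47 and 8.68 on the uninjected arrays and 10.28 and 10.99 on the injected arrays given water. The covariate thus largely goes with this contrast, so the sign changes cannot tell injection from hybridization level.

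By limma, 0 of 19011 genes passed between injected and uninjected lungs, and 1092 had an unadjusted p under 0.05 (598 higher, 494 lower), where 951 would by chance. The genes with the smallest p, none of which passed (adjusted p = 0.72 for each, limma with Benjamini-Hochberg), were Speer4d, Btbd35f20, Ipw, Btbd35f9 and Gorasp2 on the higher side and Mettl5, Tas2r102, Tle6, Dyrk4 and Lrrc38 on the lower side. The widest of these differences were 3.85 (SE 1.05) for Ipw and -3.84 (SE 0.95) for Mettl5. Arrays of both groups did not overlap for 34.3% of genes, and 33.3% would not by chance. The hybridization controls, bacterial and phage transcripts added to the hybridization mix, were also higher on the injected arrays, with the cre control at 13.04 ± 0.47 (SD, n = 2) in injected and 10.77 ± 0.35 (SD, n = 2) in uninjected mice given water.

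**Figure D2:**
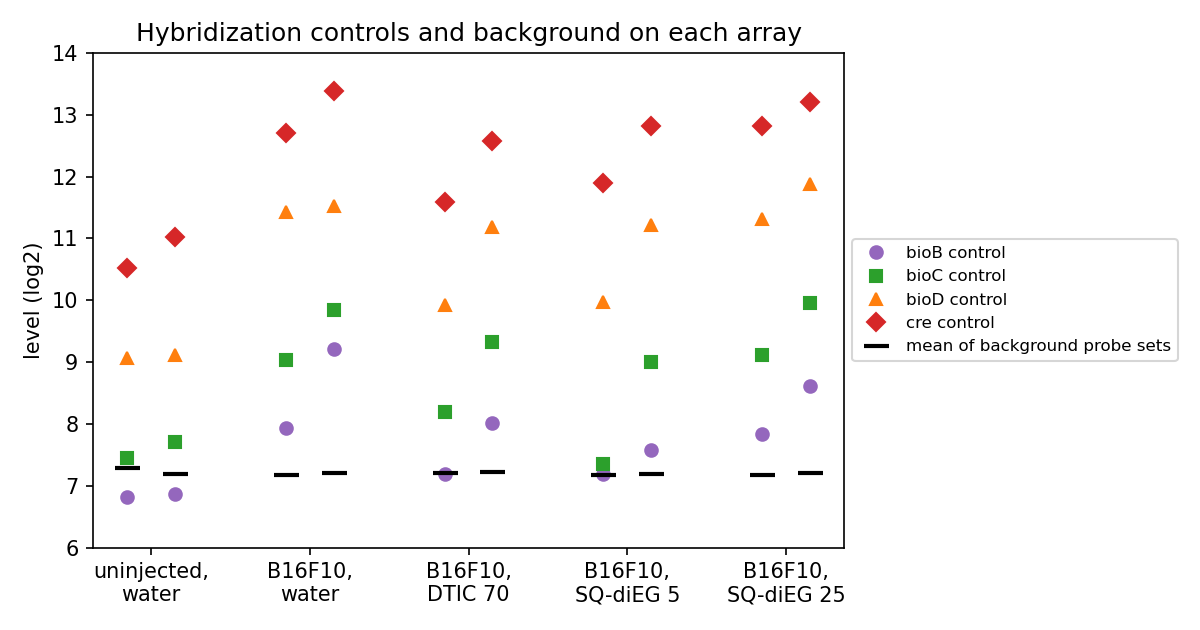
Log2 levels (y axis) of the 4 hybridization controls and the mean of the background probe sets on each of the 10 arrays, by group. The cre control averaged 10.77 on the 2 uninjected arrays and 12.63 on the 8 injected arrays.

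The second comparison asks what DTIC changed in injected mice. Of the 5 pigment cell markers, 3 were lower under DTIC by over 1 log2 unit, where the SD of the difference over all 19011 genes was 0.984. All 5 exceeded the negative controls' 95th percentile on 0 arrays, and the injected arrays given water are those of the first comparison. Pmel averaged 7.65 ± 1.08 (SD, n = 2) with DTIC and 9.44 ± 0.35 (SD, n = 2) with water, a log2 difference of -1.78 (SE 0.97), Tyrp1 differed by -1.58 (SE 0.97) and Mlana by -1.36 (SE 0.95). Dct and Tyr differed by 0.02 (SE 0.94) and -0.17 (SE 1.02), and Slc45a2, a transporter of pigment cells, by 1.46 (SE 0.95). None of these passed, and the 24 melanocyte and melanoma genes split into 11 higher and 13 lower (adjusted p = 0.941 from limma's camera). In the p53 and DNA damage list, Xpc, a sensor of damaged DNA in nucleotide excision repair, averaged 6.00 ± 0.40 (SD, n = 2) with DTIC and 9.61 ± 0.67 (SD, n = 2) with water, a log2 difference of -3.62 (SE 0.96). It passed when adjusted over the list alone (limma adjusted p = 0.0134), the 1 gene of the 35 to do so, and not over all genes (adjusted p = 0.743). Over the 38 lists and 6 comparisons, 6 of 228 such tests within a list had a member that passed, each 1 gene, where 11.4 would by chance with no change at all. All 6 genes, named here and below, exceeded the 95th percentile of the negative controls on 0 arrays, and in all 6 the lower group mean lay under the background probe sets. Gadd45a differed by -2.94 (SE 0.99), Ccng1 by -1.84 (SE 0.94), Plk3 by 1.62 (SE 1.00) and Cdkn1a by 0.17 (SE 1.01). The list held 19 genes higher and 16 lower, its median was 0.17 and its mean -0.14, and its adjusted camera p was 0.941.

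Among proliferation genes 22 were higher and 15 lower with DTIC. The mitotic genes Hmmr, Cenpe and Aurka differed by -1.99 (SE 0.94), -1.59 (SE 0.94) and -1.66 (SE 1.00), E2f1 by -1.86 (SE 0.96) and Mki67 by 1.08 (SE 0.97). The list's median was 0.20 and its mean -0.03, and no member passed over all genes or adjusted over the list alone. Of 25 B and plasma cell genes 14 were lower, with the immunoglobulin joining chain Jchain at -2.07 (SE 0.97), the B cell transcription factor Ebf1 at -1.95 (SE 0.95), Chst3 at 1.60 (SE 0.96) and Cd72 at 1.54 (SE 0.99). Genes of fatty acid synthesis and lipid handling were lower for 18 of 26, with Gpam, Acaca, Cd36 and Plin2 at -1.58, -1.41, -1.38 and -1.34, a mean of -0.44 and an adjusted p = 0.941 from limma's camera. MHC class I genes were higher for 15 of 22, with H2-Q1 at 1.79 (SE 0.96), H2-D1 at -1.60 (SE 0.95), H2-T23 at 1.56 (SE 0.97) and Psmb10 at 1.30 (SE 0.96). Camera gave them an adjusted p = 0.941 and fry 0.017. Both this value and the one for injection use the same injected arrays given water.

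Between DTIC and water 0 of 19011 genes passed by limma, with 925 at an unadjusted p under 0.05 (432 higher, 493 lower) and 951 by chance. The smallest p belonged to Gpr45, Tmbim6, Ric1, Olfr194 and Cetn2 among genes higher with DTIC and to Btbd35f4, Btbd35f9, Speer4d, Xpc and Espl1 among genes lower, all at an adjusted p = 0.743. Gpr45 differed by 3.95 (SE 0.94) and the separase gene Espl1 by -3.49 (SE 0.94). Sqle differed by -0.15 (SE 0.95) and Sftpc by 0.55 (SE 0.97).

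The third comparison asks what SQ-diEG at 5 mg/kg per day changed in injected mice. Immediate early genes, which cells induce within minutes of a stimulus, were lower for 21 of 29 members. The transcription factor genes Myc and Egr1 averaged 6.13 ± 0.41 and 5.62 ± 0.39 (SD, n = 2) with the compound and 8.52 ± 1.64 and 7.92 ± 1.10 (SD, n = 2) with water. Their log2 differences were -2.39 (SE 0.96) and -2.31 (SE 0.95), those of Ccn1 and Dusp2 -1.59 (SE 0.98) and -1.44 (SE 0.95). The list's mean was -0.64. It was under a p of 0.05 before adjustment and did not pass after it (limma's camera, Benjamini-Hochberg adjusted p = 0.142), and the adjusted p = 0.835 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Fatty acid and lipid genes were lower for 19 of 26, with Plin2 at -2.06 (SE 0.97), the carnitine transferase Cpt1a at -1.90 (SE 0.98), Lpcat3 at -1.41 (SE 0.97) and Thrsp at -1.18 (SE 0.96). Their mean was -0.51, and the list was under a p of 0.05 before adjustment and did not pass after it (limma's camera, adjusted p = 0.691), and the adjusted p = 0.993 with an estimated correlation. Again no member passed.

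Of 20 genes of cholesterol synthesis, 11 were higher and 9 lower at 5 mg/kg. Mevalonate kinase, Mvk, differed by 2.26 (SE 0.96), Cyp51 by -1.67 (SE 0.96), the squalene synthase gene Fdft1 by -1.49 (SE 1.01), Ggps1 by 1.27 (SE 0.94) and Sqle by -0.20 (SE 0.95). Pmel averaged 8.06 ± 0.37 (SD, n = 2), a log2 difference of -1.38 (SE 0.97) from water, and Mlana, Tyr, Tyrp1 and Dct differed by -0.41, -0.93, 0.67 and 0.18. Of the 24 pigment cell genes 15 were lower, with Slc24a5 at -2.13 (SE 0.97), Cd63 at 2.05 (SE 0.98), Slc45a2 at 1.41 (SE 0.95) and Ptgds at -1.40 (SE 0.97). For both lists camera's adjusted p was 0.993 and no member passed over all genes or adjusted over the list alone. MHC class I genes were higher for 13 of 22, with H2-T23 at 2.38 (SE 0.97), H2-D1 at -1.74 (SE 0.95), H2-K1 at 1.42 (SE 0.94) and B2m at 1.46 (SE 0.97). Camera gave an adjusted p = 0.93 and fry 0.0229. The p53 list was split 17 to 18, with Ckap2 at -2.11 (SE 0.97), Ercc5 at -1.54 (SE 0.96), Xpc at -1.40 (SE 0.96) and Epha2 at -1.34 (SE 0.95). Its adjusted p was 0.993 by camera and 0.0333 by fry, and no member of either list passed over all genes or adjusted over the list alone.

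By limma 0 of 19011 genes passed at 5 mg/kg against water, with 1005 at an unadjusted p under 0.05 (450 higher, 555 lower) and 951 by chance. The genes with the smallest p, none of which passed, were Tha1, Tpcn2, Slco1b2, Pax6 and Dus1l on the higher side and Olfr610, Ccdc157, R3hdm1, Elovl4 and Tas2r116 on the lower side. Tha1 averaged 9.93 ± 0.01 (SD, n = 2) with the compound and 5.93 ± 0.14 (SD, n = 2) with water, and the olfactory receptor gene Olfr610 differed by -4.32 (SE 0.98). Their adjusted p in limma was 0.922 and 0.886. The lower mean of each, 5.93 for Tha1 with water and 6.29 for Olfr610 with the compound, lay under the background probe sets. They exceeded the negative controls' 95th percentile on 0 and 1 arrays. Mki67, Cdkn1a and Sftpc differed by -0.57 (SE 0.97), -0.06 (SE 1.01) and 1.35 (SE 0.97).

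The fourth comparison asks the same of SQ-diEG at 25 mg/kg per day. The surfactant protein gene Sftpc averaged 9.10 ± 0.47 (SD, n = 2) with the compound and 6.34 ± 0.93 (SD, n = 2) with water, a log2 difference of 2.77 (SE 0.97). It did not pass limma's test (Benjamini-Hochberg adjusted p = 0.941). In its list of 26 type II cell genes 15 were higher, with Egfl6 at 2.14 (SE 0.95), Muc1 at -1.57 (SE 0.98) and Rab27a at -1.43 (SE 0.94). Pmel averaged 7.94 ± 1.46 (SD, n = 2), a log2 difference of -1.50 (SE 0.97), and Mlana, Tyrp1, Dct and Tyr differed by -1.81 (SE 0.95), -1.73 (SE 0.97), -0.95 (SE 0.94) and -0.29 (SE 1.02). Other pigment cell genes went the other way, Rab38 by 2.50 (SE 0.93) and Slc45a2 by 2.20 (SE 0.95), and the 24 genes split into 11 higher and 13 lower. Mki67, a marker of dividing cells, averaged 9.50 ± 0.02 (SD, n = 2) against 7.60 ± 0.59 (SD, n = 2), a log2 difference of 1.90 (SE 0.97). With Birc5 at 2.08 (SE 0.94), Mcm5 at 1.97 (SE 0.97) and Cdt1 at -1.69 (SE 0.97), 19 of 37 proliferation genes were higher. Camera's adjusted p was 0.948 for each of these lists, and no member passed over all genes or adjusted over the list alone.

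Of 20 cholesterol synthesis genes 15 were higher at 25 mg/kg and 5 lower. Idi1 differed by 2.18 (SE 0.98), Mvd by -2.07 (SE 0.98), the cholesterol transfer protein gene Stard4 by 1.53 (SE 1.03), Lss by -1.38 (SE 0.94) and Sqle by 0.06 (SE 0.95). Immediate early genes were lower for 20 of 29, with Nr4a3 at -2.02 (SE 0.93), Egr1 at -1.55 (SE 0.95) and Jun at -1.26 (SE 0.96), while the phosphatase Dusp1 stood at 2.77 (SE 0.97). In the list of oxidative phosphorylation the ATP synthase subunit gene Atp5o averaged 5.70 ± 0.36 (SD, n = 2) with the compound and 9.17 ± 0.47 (SD, n = 2) with water, a log2 difference of -3.47 (SE 1.02). It passed when adjusted over the list alone (limma adjusted p = 0.0398), within the number of such passes that chance gives, and not over all genes (adjusted p = 0.941). Cox5b differed by -2.22 (SE 0.96), Cox7a2 by 2.04 (SE 0.96) and Uqcrb by 1.96 (SE 0.93), and 13 of the 32 genes were higher. The adjusted camera p was 0.948 for the 3 lists, and fry gave an adjusted p = 0.0225 for MHC class I genes, again against the same injected arrays given water.

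By limma 0 of 19011 genes passed at 25 mg/kg against water, with 997 at an unadjusted p under 0.05 (487 higher, 510 lower) and 951 by chance. The anion transporter gene Slco6c1 came closest, at 10.52 ± 1.25 (SD, n = 2) against 5.78 ± 0.15 (SD, n = 2). Its log2 difference was 4.74 (SE 0.95) and its limma adjusted p = 0.122. The lower of these means lies under the background probe sets and the gene exceeded the negative controls' 95th percentile on 1 array, so the size of the difference is not measured from a detected level. Tulp2, Eif3c, Bcat1 and Lce1k followed on the higher side and Sclt1, Gml, Ssh2, Fam71b and Spata31 on the lower side, none of which passed. Cdkn1a differed by -0.02 (SE 1.01).

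**Figure D3:**
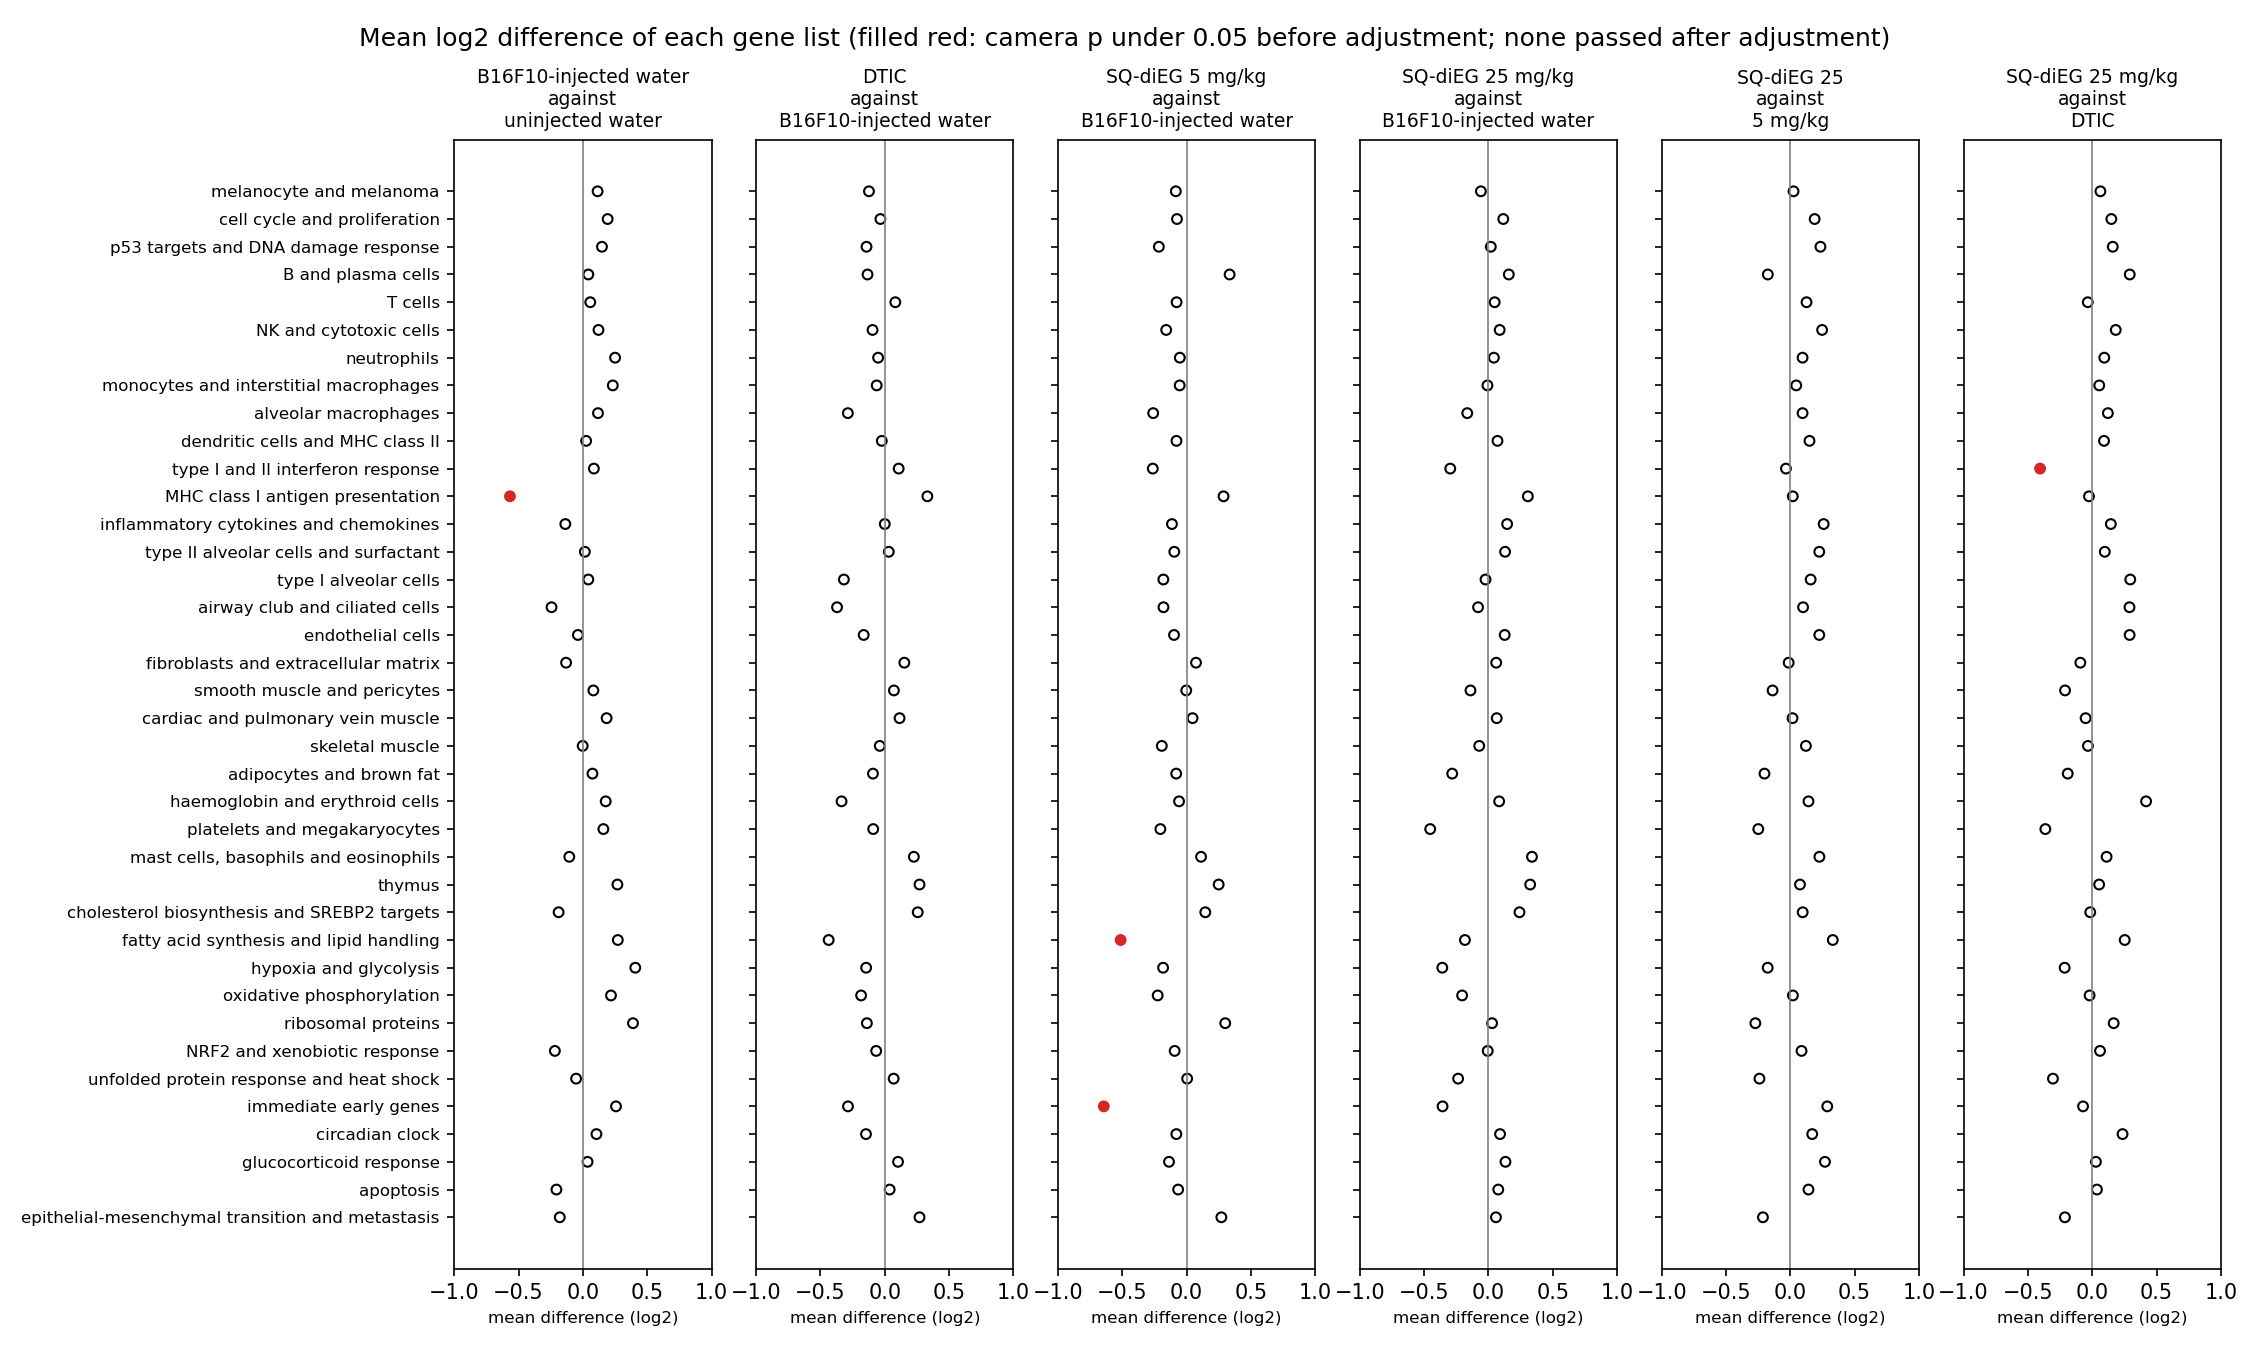
Mean log2 difference (x axis) of each of the 38 gene lists (rows) in the 6 comparisons (panels), with red points where camera's p was under 0.05 before adjustment. The means ran from -0.64 to 0.42 and no list passed after Benjamini-Hochberg adjustment.

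The 2 doses of SQ-diEG were also set against each other. Mki67 averaged 9.50 ± 0.02 (SD, n = 2) at 25 mg/kg and 7.02 ± 0.61 (SD, n = 2) at 5 mg/kg, a log2 difference of 2.47 (95% interval 0.53 to 4.42 before any correction for the number of genes). Tyrp1 differed by -2.40 (95% interval -4.34 to -0.47) and Pmel by -0.12 (95% interval -2.06 to 1.81), while Mlana, Dct and Tyr differed by -1.41, -1.13 and 0.63. Rab38, which takes part in the transport of melanosome cargo, averaged 10.10 at the higher and 7.09 at the lower dose. Its difference of 3.01 (SE 0.93) passed when adjusted over the melanocyte list alone (limma adjusted p = 0.0483), as did the surfactant protein gene Sftpa1 in its list at 3.25 (SE 0.95, adjusted p = 0.0317). The B cell adaptor gene Bank1 likewise passed in its list at 3.70 (SE 0.98, adjusted p = 0.00939). These 3 passes are among the 6 over all comparisons, where chance would give 11.4. That number is for all 228 tests and not for this comparison alone. Over all genes the limma adjusted p was 0.909 for Rab38 and Sftpa1 and 0.893 for Bank1. Other B cell genes were lower at the higher dose, among them Pax5 at -2.28 (SE 0.94), H2-Ob at -1.98 (SE 0.95) and Cd22 at -1.79 (SE 0.96), and 15 of the 25 were lower.

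Of the other lists at the 2 doses, 22 of 37 proliferation genes were higher at 25 mg/kg, with Cdt1 at -2.89 (SE 0.97), Top2a at 1.84 (SE 0.98) and Birc5 at 1.56 (SE 0.94). In the type II cell list 16 of 26 were higher, with Sfta2, Lpcat1, Muc1 and Sftpc at 1.72, 1.65, -1.54 and 1.42. The p53 list had 22 of 35 higher, with Aen at 1.93 (SE 0.98), Gadd45b at 1.73 (SE 0.93), Xpc at -1.74 (SE 0.96) and Dglucy at 1.75 (SE 0.98), and fry gave it an adjusted p = 0.0495 where camera gave 0.912. Cholesterol synthesis genes were higher for 11 of 20, with Stard4, Srebf2, Idi1 and Mvk at 2.15, 1.64, 1.67 and -1.62, and Sqle at 0.27. Camera's adjusted p was 0.912 for proliferation, type II and B cell genes, 0.974 for cholesterol synthesis and 0.984 for pigment cells, whose mean of 0.03 and camera direction differed in sign. No proliferation, p53 or cholesterol gene passed over all genes or adjusted over the list alone. By limma 0 of 19011 genes passed between the doses, with 983 at an unadjusted p under 0.05 (548 higher, 435 lower) and 951 by chance. The smallest p belonged to Lce1k, Pip4k2b, Hivep2, Bank1 and Olfr69 on the higher side and Faf1, Sdhaf1, Ap1m1, Sprr2k and Toe1 on the lower side, and none passed. Cdkn1a differed by 0.04 (SE 1.01).

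The last comparison set SQ-diEG at 25 mg/kg against DTIC at 70 mg/kg per day, so the doses differed as well as the compounds. Interferon response genes were lower with SQ-diEG for 25 of 41 members. Oasl1, Isg15, Ifih1 and Irgm2, all induced by interferon, differed by -2.38 (SE 0.99), -2.25 (SE 0.95), -2.06 (SE 0.95) and -1.78 (SE 0.97). The list's mean was -0.41, and it was under a p of 0.05 before adjustment and did not pass after it (limma's camera, Benjamini-Hochberg adjusted p = 0.859), and the adjusted p = 0.933 with an estimated correlation. No member passed over all genes or adjusted over the list alone. In the circadian list Bhlhe40, a repressor of the clock, averaged 9.19 ± 0.87 (SD, n = 2) with SQ-diEG and 6.11 ± 0.17 (SD, n = 2) with DTIC. Its difference of 3.08 (SE 0.95) passed when adjusted over the list alone (limma adjusted p = 0.042), again within the number that chance gives, and not over all genes (adjusted p = 0.865). Fkbp5, Nr1d2 and Usp2 differed by 2.23 (SE 0.98), 2.00 (SE 1.02) and -1.23 (SE 0.97), and 11 of 21 genes were higher. Sftpc differed by 2.22 (SE 0.97).

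Of the pigment cell markers, the log2 differences were 0.28 for Pmel (95% interval -1.65 to 2.22), -0.16 for Tyrp1, -0.46 for Mlana, -0.97 for Dct and -0.13 for Tyr, intervals too wide to call the treatments alike. Rab38 differed by 2.40 (SE 0.93), Gpnmb by -1.74 (SE 1.04), Tspan10 by 1.49 (SE 0.94) and Cd63 by 1.03 (SE 0.98), and the 24 genes split into 11 higher and 13 lower. Of 35 p53 genes 18 were higher, with Trp53inp1 at 2.29 (SE 0.98), Sesn2 at -2.10 (SE 0.97), Aen at 2.02 (SE 0.98) and Perp at 1.91 (SE 0.94). Cholesterol synthesis genes were split 10 to 10, with Stard4, Lss, Srebf2 and Insig1 at 2.43, -2.08, 1.73 and -1.68. Of 25 B and plasma cell genes 13 were higher, with Ly6d at 2.68 (SE 0.97), Bank1 at 2.05 (SE 0.98), Cd22 at -1.35 (SE 0.96) and Jchain at 1.32 (SE 0.97). Camera's adjusted p was 0.973 for pigment cells and cholesterol synthesis, 0.878 for the p53 and circadian lists and 0.859 for B cells. No member of the pigment cell, p53, cholesterol or B cell lists passed over all genes or adjusted over the list alone. The pigment cell list had a median of -0.14 and a mean of 0.06, and the cholesterol list a median of 0.02 and a mean of -0.01. Mki67, Cdkn1a and Sqle differed by 0.82 (SE 0.97), -0.20 (SE 1.01) and 0.22 (SE 0.95).

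By limma 0 of 19011 genes passed between SQ-diEG and DTIC, with 1004 at an unadjusted p under 0.05 (499 higher, 505 lower) and 951 by chance. Nfyc, a subunit of a CCAAT-binding factor, and the olfactory receptor gene Olfr830 came closest, at 4.40 (SE 0.95) and -4.37 (SE 0.94), both with a limma adjusted p = 0.221. Nfyc averaged 5.59 with DTIC, under the background probe sets, and exceeded the negative controls' 95th percentile on 0 arrays. Gpr37, H2-T-ps, Clec4a1 and Rps27l followed on the higher side and Sprr2k, Spata31, Dcun1d3 and Tmbim6 on the lower side, none of which passed. Olfr830 passed in limma, with an adjusted p = 0.0406, when only the 3099 genes above the array median on at least 8 arrays were tested, a filter chosen after the data were seen. That filter admits genes that are low in 1 group of 2 arrays, so it depends on the differences tested. Olfr830 was the only gene to pass a test adjusted over all genes tested under any setting. Of 99 other splits of the arrays, 2 gave an adjusted call in the regrouped injection contrast over the 19011 genes. Those splits used neither that filter nor the contrast against DTIC, so they give no chance rate for the Olfr830 call.

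Finally, genes were sought that injection and a treatment moved in opposite directions. By limma no gene passed for injection or for any of the 3 treatments, so none could pass both tests. The 3 comparisons share the injected arrays given water with the injection comparison, which makes opposite differences frequent with no effect at all. Across genes, which are not independent replicates, the correlation of the log2 differences was -0.524 for DTIC, -0.517 for 5 mg/kg and -0.462 for 25 mg/kg. Simulated arrays with no effect gave -0.499, -0.501 and -0.50. The covariances were -0.525, -0.524 and -0.467, against simulated values of -0.47 (SD 0.008), -0.472 (SD 0.009) and -0.471 (SD 0.007). The simulation drew genes independently, so these SDs leave out any correlation between genes and cannot show an excess. Part of any excess may come from those shared arrays. They were therefore also split, 1 array for injection and the other for the treatment, in both ways, a setting chosen after the data were seen. Across genes, which are not independent replicates, the correlations were then -0.011 and -0.031 for DTIC, -0.004 and -0.037 for 5 mg/kg and 0.035 and -0.001 for 25 mg/kg. The covariances were -0.017 and -0.046, -0.006 and -0.055, and 0.053 and -0.001, against simulated values of -0.003 to 0.003 (SD 0.008 to 0.013) from genes drawn independently. By limma no gene passed either test in any split, so the count of opposite calls could only be 0. Pmel stood at 2.93 for injection and at -1.78, -1.38 and -1.50 for the 3 treatments, which rest on the same arrays and did not pass.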

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

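The tests of the hybridization controls, of failed hybridization and of detached probe set names were chosen after the results were seen, and the hybridization covariate after the data were seen. For 3 of the 4 hybridization controls, which no comparison between groups used, levels were higher on all 8 injected arrays than on both uninjected ones. The difference of the means was 1.11 for bioB, 1.97 for bioD and 1.85 for cre on the log2 scale. For bioC it was 1.40, with an overlap. The two-sided exact permutation p over the 45 splits was 0.0667, 0.0222, 0.0222 and 0.0889, and the adjusted exact p over 10 control quantities was 0.111 for the first 3 and 0.127 for bioC. Of the other quantities, the injected minus uninjected difference was -0.13 for the ERCC controls, 0.27 for probe sets with no gene listed and 1.06 for probe sets with mitochondrial-chromosome identifiers (exact p = 0.0444, 0.0444 and 0.0667, adjusted 0.111 each). It was -0.07 for the poly-A controls, -0.05 for the background and 0.06 for the negative controls (adjusted exact p = 0.333, 0.139 and 0.198). The 9 probe sets with mitochondrial-chromosome identifiers averaged 16.36 to 18.68 per array, where the background probe sets averaged 7.17 to 7.29. Their difference thus lies above 16, at the upper end of the scale, whose making is unknown.

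The first pattern is that lung and melanoma markers lay close to background on every array. Probe sets outside the controls were not all dim, as those with mitochondrial-chromosome identifiers averaged 16.36 or more on every array. Failed hybridization or staining is argued against by the cre control, which stood at least 3.23 log2 units above the background probe sets. That control was added to the hybridization mix, so it says nothing of how the sample RNA was labelled. The poly-A controls averaged 4.55 to 4.78 per array, under the background probe sets at 7.17 to 7.29. What their low level means was not tested. Probe set names detached from their signals across the whole table are argued against by bioB, bioC, bioD and cre, which rose in the order of their added amounts on 10 of 10 arrays; this leaves open gene probe sets alone. It stays open whether the labelled strand may be one that the probes do not pair with: the labels describe antisense target from a 3' kit, the identifiers have the form of whole-transcript arrays, and genes named as opposite-strand transcripts stood above the array median on all arrays no more often than other genes beyond chance (1 of 16, one-sided Fisher's exact p = 0.355), too few to decide. No biological explanation was tested.

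The second pattern is the count of 1092 genes at an unadjusted p under 0.05 between injected and uninjected lungs, the highest of the 6 comparisons. Of 100 splits of the arrays into 5 pairs, 14 gave as many genes, the real one included, with 1304 as the highest other, so chance is not excluded. With the mean hybridization control level as a covariate the count was 884, below the 951 that chance gives, so the hybridization level of the arrays may also account for it. That level differed between the groups, and an effect of the injected cells stays open as well.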

How the results depend on the processing

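No gene passed limma's adjusted test in any of the 6 comparisons under the planned normalizations, filters, probe set rules, prior, weights, fits of only the compared groups or an adjusted p under 0.10, and leaving out each array gave 0 to 0 genes, lists and opposite calls. These counts were 0 with all arrays, so they do not show how the differences move. A left-out array leaves a group with 1, assumed to vary like the others. With a fold of at least 2 and an unadjusted p under 0.05, the counts were 1092 for injection, 925 for DTIC, 1005 and 997 for SQ-diEG at 5 and 25 mg/kg, 983 between doses and 1004 against DTIC. That rule corrects for no number of tests, and its fold removed 0 genes that the p alone gave. At it, 238, 228 and 177 genes went opposite ways under injection and DTIC, 5 and 25 mg/kg, where simulated arrays with no effect gave 160 to 209, 160 to 223 and 155 to 198 and independent lists 26.6, 28.9 and 28.6. The simulation drew genes independently, whereas other splits of the real arrays gave 749 to 1304 genes at an unadjusted p under 0.05 by limma. The simulated ranges may thus be too narrow and cannot show an excess. Of the alternatives added after seeing the data (water arrays split between injection and treatment, hybridization level as a covariate, arrays scaled to 1 spread, genes above the median on at least 8 arrays), the last called 1 gene, Olfr830, against DTIC, with fewer genes tested. Fry called 1 list for injection, 1 for DTIC, 2 for 5 mg/kg, 1 for 25 mg/kg and 1 between doses. It sets no list against other genes. All its calls were for the MHC class I and p53 lists, whose means varied little between arrays of a group. The SDs were 0.01 to 0.07 for MHC class I and 0.01 to 0.06 for p53. So small a spread may itself be chance. The replicate block called 0 genes and 0 lists. Same-numbered arrays correlated at -0.022 to 0.05 in their deviations. This cannot exclude a pairing, as the arrays shared little of any kind. In gene levels, a measure other than deviations, arrays of the same group averaged a correlation of only 0.211 and arrays of different groups 0.202. In each of the 5 groups all 4 hybridization controls were higher on the array numbered 2, so the replicate number went with the hybridization level. Of 255 named differences, 36 changed sign under some setting, none of them past the threshold. Besides the 9 named for injection, they were Tyr, Dct, Mki67, Cdkn1a, Sqle and Sftpc for DTIC, Tyrp1, Dct, Mlana, Cdkn1a and Sqle for 5 mg/kg, Stard4, Tyr, Cdkn1a and Sqle for 25 mg/kg, Pmel, Tyr, Cdkn1a and Sqle between doses, and Gpnmb, Pmel, Tyr, Tyrp1, Mlana, Mki67, Cdkn1a and Sqle against DTIC, each with some single array left out. The median difference over genes for injection, 0.054, was -0.01 with quantile normalization, 0.001 with arrays centred on their medians or scaled to 1 spread, -0.012 with the hybridization covariate and 0.146 in the genes above the median on at least 8 arrays. Leaving out 1 of the 4 arrays compared gave 0.003 to 0.106.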

Other observations

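All tests in this part were chosen after the data were seen. Some genes held a repeatable place on the arrays although most did not. Of 19505 genes, 527 lay above the median of gene probe sets on all 10 arrays, where independent arrays would give 19, and 259 lay below it on all 10, with the same chance count. Only the higher ones are described here. Named after their values were seen, they included the chromatin proteins Hmgb1 at 11.08 ± 1.17 and Cbx3 at 10.90 ± 1.43 (SD over 10 arrays), the thymosin precursor Ptma at 10.59 ± 1.47, the ribosomal protein genes Rpl7a at 10.50 ± 1.19 and Rpl29 at 10.26 ± 1.87, and Gapdh of glycolysis at 10.15 ± 1.09. With them stood many genes not known for expression in lung, among them vomeronasal and olfactory receptor genes by symbol. Examples are the vomeronasal receptor Vmn1r250 at 10.58 ± 1.16 and the hair keratin-associated Krtap6-5 at 10.94 ± 1.19. Some pairs of similarly named genes had the same mean, SD, lowest and highest value. Vmn1r100 and Vmn1r148 both stood at 9.05 ± 0.78, and Defa2 and Defa33 both at 8.96 ± 0.53. The 527 may thus not all be separate measurements. Pold2, a DNA polymerase subunit, and Tchp exceeded the negative controls' 95th percentile on 9 arrays each, and Gm20854 and Gm20852 on 8 each.

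A candidate explanation is that abundant housekeeping transcripts were read by their probes. Of 95 genes of the ribosomal protein, glycolysis and oxidative phosphorylation lists, 6.32% lay above the median on all arrays (exact binomial 95% interval 2.35% to 13.24%), namely Rpl11, Rplp1, Cox5b, Gapdh, Eno1b and Tpi1. That is more often than other genes (one-sided Fisher's exact p = 0.0438, not corrected). However, Eno1b entered by a synonym match in place of the listed gene Eno1, and the test was not run without it. The lists also lack genes such as Rpl7a and Rpl29. Over all ribosomal protein genes by symbol, a set chosen after some members were seen, 7 of 61 did so (11.48%, exact binomial 95% interval 4.74% to 22.22%, one-sided Fisher's exact p = 0.00125, not corrected). As members already seen prompted that set, its p gives no independent support. Both shares lay under the 50% that was taken, after the data were seen, as the mark of this explanation. The explanation stays open. For transcripts of the main lung cell types, 0.91% of 110 genes did so, the 1 gene being Sec14l3, and Fisher's exact p = 0.951. None of the 38 lists passed Fisher's exact test after Benjamini-Hochberg adjustment, hypoxia and glycolysis having the smallest p = 0.0504. Effects of probe sequence, probes shared between genes among them, stay open, as the probe sequences were not used here.

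Over the 945 ways to put the arrays into 5 pairs, the real groups' mean correlation of deviations across the genes tested was as high or higher in 265, an exact one-sided p = 0.28. For the 2634 probe sets with no gene listed it was reached by 18 pairings, an exact one-sided p = 0.019 and 0.076 after Benjamini-Hochberg adjustment over 4 such tests. In the negative-control probe sets the exact p was 0.16, and with the hybridization level regressed out of the genes 0.937.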
